A study of Mus musculus with 12 samples.

How the data were processed

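Gene expression was measured in 12 samples of differentiated 3T3-L1 adipocytes on Affymetrix arrays, 3 samples in each of 4 groups defined by the adenoviral shRNA (control or against TBLR1) and by treatment with isoproterenol (none or 10 µM for 3 h). Biotinylated cRNA was prepared by the array maker's protocol, per the labels' protocols. The deposited values are log2 expression levels per probe set. The scale was read from the values, since their range of 5.391 to 14.58 is that of log2 data. The values had already been quantile normalised between arrays when deposited, as the sorted values of any 2 arrays differed by at most 0.00781. The background correction and the summarisation of probes into probe sets are not given in the sources used here. Quantile normalisation gives every array the same distribution, so a shift of most transcripts in one direction would be removed and each change is relative to the bulk of genes. No further normalisation was applied, no value was missing, and no pair of arrays shared a larger fraction of identical values than 0.0095.

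The table held 16553 probe sets, of which 61 were control probe sets. The platform annotation, which can be old, gave 15270 probe sets 1 gene symbol and none to 1222, which were left unnamed and kept out of the tests of genes. For the 3 genes with 2 probe sets the one with the higher mean level was used, which left 15267 genes. An array gives no count, so precision rests on the number of arrays and on the spread between them. The median SD of a gene within a group was 0.0486 to 0.0531 on the log2 scale.

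Groups were taken from the sample labels. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, which left 8 residual degrees of freedom per gene, and variances were moderated with eBayes (7.38 prior degrees of freedom). There were 5 contrasts: TBLR1 against control shRNA without and with isoproterenol, isoproterenol against no treatment with each shRNA, and the difference between these responses. P-values were two-sided and were adjusted by the method of Benjamini and Hochberg over all genes within a contrast, and an adjusted p under 0.05 was called. Every adjusted p of a gene is from this limma model. The comparisons between groups that share an array rest partly on the same values; the 2 shRNA comparisons, and the 2 isoproterenol comparisons, share none.

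Before the data were examined, 36 lists of genes were written (868 genes, 731 of them measured), covering pathways of adipocytes and of β-adrenergic signalling, other cell types and stress responses. Lists were tested with camera at its preset correlation of 0.01, which compares the members with all other genes, and adjusted over the lists within a contrast. Camera with a correlation estimated per list and fry, which tests whether the members move on balance in one direction, were alternatives. Counts of members that rose or fell use the adjustment over all genes, and a second adjustment over the members of the list alone is given beside them. Symbols absent from the annotation were matched through the synonyms of a RefSeq gene table. The lists overlap in part and some markers of other cell types are also expressed by adipocytes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

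The genes named were chosen by a rule, also fixed before the data were examined. It took Tbl1xr1 and its corepressor partners. Per comparison of groups it took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap. Per list it took up to 4 called members with the largest changes, or up to 2 with the smallest p where none was called, and for the difference between responses it took the 12 largest. The text names part of these. Genes named outside the rule are said to have been chosen after their values were seen.

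The models were tested on simulated data before use, with values drawn from the real means and spreads of the 15267 genes and 200 genes changed by known amounts. For TBLR1 shRNA without isoproterenol 85.1% of the genes changed by 1.25-fold were called and 100% of those changed by 1.5-fold, and 5 unchanged genes were called. For TBLR1 shRNA with isoproterenol these values were 83.6%, 100% and 9, for isoproterenol with control shRNA 89.6%, 100% and 11, and for isoproterenol with TBLR1 shRNA 88.1%, 100% and 11. For the difference between responses 53.7% of genes changed by 1.25-fold, 94% of those changed by 1.5-fold and 98.5% of those changed by 2-fold were called, with 8 unchanged genes. A list shifted by 0.2 was called in each of the 5 contrasts and no unshifted list was; the simulated genes were independent of one another, so this says nothing of lists whose members vary together.

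The alternatives fixed in advance were median centring, eBayes with trend and robust settings, only the arrays of the groups compared, a replicate block, array weights, leaving out the lowest 33% of genes by level, the mean of several probe sets, an adjusted p under 0.01, a change of at least 1.5-fold, the other tests of lists, and leaving out each array in turn. Cyclic loess, centring on the 18 bacterial hybridisation control probe sets and a fit that also held the unnamed probe sets were added after seeing the data. Exact permutation tests were used for single measures.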

Results

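The samples were 3T3-L1 adipocytes, fat cells differentiated from a mouse fibroblast line. On day 9 of differentiation the cells had been given adenovirus carrying a control shRNA or an shRNA against TBLR1 at a multiplicity of infection of 500. TBLR1, the product of the gene Tbl1xr1, is a subunit of the NCoR and SMRT corepressor complexes and takes part in the exchange of corepressors for coactivators at nuclear receptors. After 3 days the cells were held in Krebs-Ringer buffer for 2 h and then left untreated or given 10 µM isoproterenol, a β-adrenergic agonist that raises cAMP and starts lipolysis, for 3 h. The series concerns the part of TBLR1 in the release of lipid from white fat cells. RNA was measured on 12 Affymetrix arrays, 3 in each of the 4 groups, and 15267 genes were tested. All 12 arrays had the same median of 7.14 on the log2 scale. Across genes, arrays of the same group correlated at 0.998 to 0.999 and arrays of different groups at 0.977 to 0.997. The first principal component, with 69.3% of the variance, separated the shRNAs, and the second, with 18.0%, separated the treatments. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Values of genes are log2 differences ± SE with n = 3 arrays per group, and adjusted p-values are those of limma after Benjamini-Hochberg adjustment.

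The targeted gene was lower in every sample given the TBLR1 shRNA. Tbl1xr1 read 7.20, 7.27 and 7.26 on the 3 control arrays without isoproterenol and 6.45, 6.47 and 6.43 on the 3 TBLR1 shRNA arrays. With isoproterenol it read 7.23, 7.34 and 7.29 against 6.48, 6.41 and 6.37. Tbl1xr1 thus fell by 0.79 ± 0.04 without isoproterenol, which left 57.7% of the control signal (adjusted p = 8.36e-10), and by 0.86 ± 0.04 with it, which left 54.9% (adjusted p = 2.3e-10). An exact permutation of the shRNA labels within each treatment gave a two-sided p = 0.005, the smallest that the 400 arrangements allow. Isoproterenol itself left Tbl1xr1 within error with the control shRNA (0.04 ± 0.04, adjusted p = 0.593) and with the TBLR1 shRNA (-0.03 ± 0.04, adjusted p = 0.77).

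The other genes of the list of corepressor partners moved by small amounts. Without isoproterenol Tbl1x, the paralogue of Tbl1xr1, fell by 0.19 ± 0.05 (adjusted p = 0.00481), the deacetylase gene Hdac3 fell by 0.14 ± 0.04 (adjusted p = 0.00662) and Cops2 fell by 0.12 ± 0.04 (adjusted p = 0.0221), whereas the β-catenin gene Ctnnb1 rose by 0.12 ± 0.04 (adjusted p = 0.0274). With isoproterenol the same genes differed by -0.24, -0.21, -0.17 and 0.17. Gps2 (0.02 ± 0.06) and Nr2c2 (0.07 ± 0.05) did not pass. Of the 7 measured members of the list, 1 rose and 4 fell, the same numbers when adjusted over the list alone. The targeted gene Tbl1xr1 is itself a member and 1 of the 4. The list as a whole, Tbl1xr1 included, was not called (median -0.12, adjusted p = 0.322). The calls of Tbl1x, Hdac3 and Cops2 ended in both treatments when arrays were centred on their bacterial hybridisation controls (without isoproterenol -0.12, -0.07 and -0.05, adjusted p = 0.128, 0.425 and 0.565; with it -0.13, -0.09 and -0.06, adjusted p = 0.0746, 0.215 and 0.457). Without isoproterenol, Cops2 and Ctnnb1 also lost their calls without control replicate 1 (adjusted p = 0.0501 and 0.0755), control replicate 2 (0.0653 and 0.069) or TBLR1 replicate 1 (0.116 and 0.108), and Cops2 after cyclic loess (0.101).

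**Figure D1:**
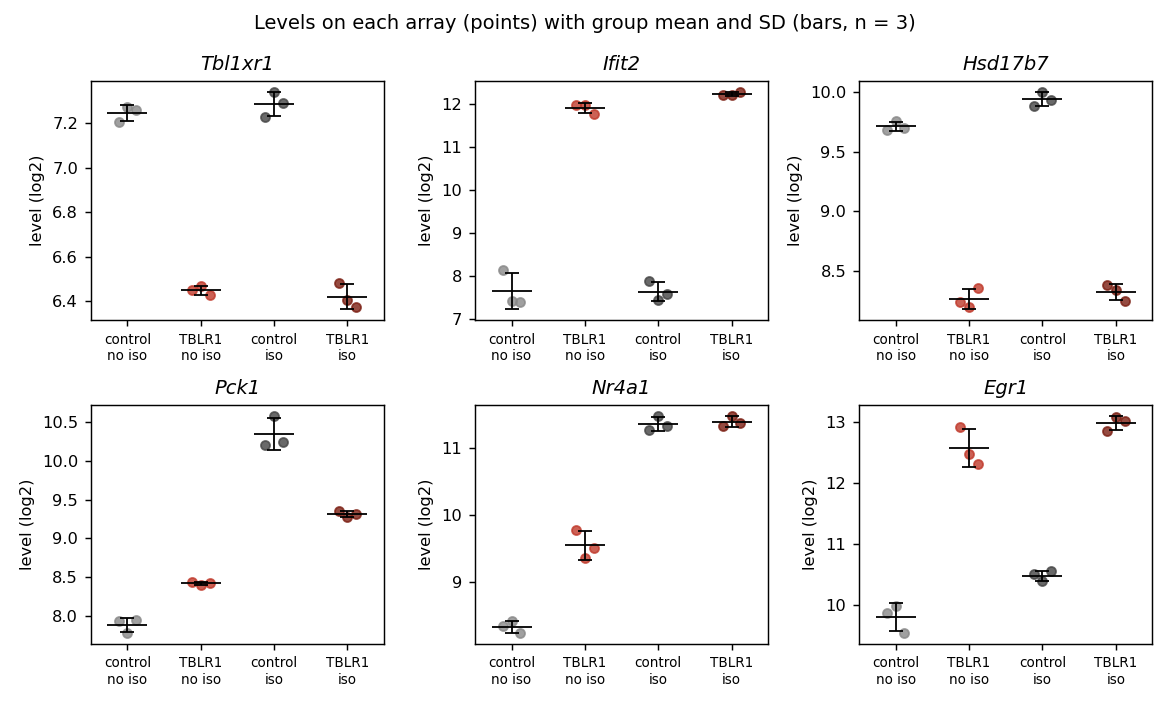
Levels (log2, vertical axes) of Tbl1xr1, Ifit2, Hsd17b7, Pck1, Nr4a1 and Egr1 on each of the 12 arrays, by shRNA and treatment with isoproterenol (iso); points are arrays and bars are group means with SD (n = 3). Tbl1xr1 was lower on all 6 arrays with TBLR1 shRNA, and Pck1 reached a mean of 10.35 with isoproterenol and control shRNA against 9.31 with TBLR1 shRNA.

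Knockdown of TBLR1 without isoproterenol was accompanied by a strong rise of interferon-induced genes. The antiviral gene Ifit2 was 18.9-fold higher (4.24 ± 0.15, adjusted p = 9.87e-12), the chemokine genes Ccl5 and Cxcl10 were 14.4-fold and 8.35-fold higher (3.85 ± 0.10 and 3.06 ± 0.17), Rsad2, which encodes the antiviral enzyme viperin, was 9.72-fold higher (3.28 ± 0.19), and the immunoproteasome gene Psmb9 was 6.1-fold higher (2.61 ± 0.05). Of 30 measured genes of the interferon response list, 28 rose and 2 fell, also when adjusted over the list alone, with a median rise of 1.88. The 2 that fell, named after their values were seen, were Ifi27 (-0.70) and Irf1 (-0.16, and -0.09 with an adjusted p = 0.299 when arrays were centred on their hybridisation controls). The list was called by camera (adjusted p = 1.58e-21), with an adjusted p = 0.211 with an estimated correlation. Of 16 measured macrophage markers, 2 rose, Cd14 (0.45 ± 0.09) and Ctss (0.27 ± 0.07), Csf1r fell (-0.12 ± 0.04, adjusted p = 0.0215) and 13 did not pass, the same numbers adjusted over the list alone. Csf1r lost its call with only the 6 arrays compared (adjusted p = 0.0512), without control replicate 1 (0.115), without TBLR1 replicate 2 (0.0777) and with hybridisation control centring (-0.05, 0.581). The median of the macrophage markers was -0.02 and their mean 0.03, and the test pointed up without a call (adjusted p = 0.776).

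Genes of sterol and fatty acid synthesis were lower in the same cells. Hsd17b7, Cyp51, Tm7sf2 and Nsdhl, which encode enzymes of the late steps of cholesterol synthesis, fell by 1.45 ± 0.05, 1.31 ± 0.05, 1.30 ± 0.06 and 1.15 ± 0.04 (adjusted p from 9.87e-12 to 1.06e-10). Of 17 measured cholesterol synthesis genes 16 fell, also adjusted over the list alone, and only Srebf2, which encodes their transcription factor, did not pass. The median was -0.92 (camera adjusted p = 2.83e-16, and adjusted p = 0.104 with an estimated correlation). In the fatty acid synthesis list 13 of 19 fell and 2 rose, or 14 and 2 adjusted over the list alone, with a median of -0.61 (adjusted p = 1.77e-06, and 0.169 as the adjusted p with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, fell by 1.20 ± 0.06 and the desaturase gene Fads2 fell by 0.98 ± 0.06. Srebf1, the transcription factor gene of this pathway, rose by 0.42 ± 0.05.

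Adipocyte markers were lower as well, while cell cycle genes were higher. Of 34 adipocyte markers 21 fell and none rose, or 25 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 1.13e-08, and adjusted p = 0.104 with an estimated correlation). Among them the adipokine genes Retn (resistin) and Agt (angiotensinogen) fell by 1.58 ± 0.09 and 1.14 ± 0.05 and the carbonic anhydrase gene Car3 fell by 1.09 ± 0.05. Breakdown genes of branched-chain amino acids, such as Pccb (-0.93 ± 0.05) and Hibch (-0.73 ± 0.07), fell in 15 of 19 cases, also adjusted over the list alone, with a median of -0.33 (adjusted p = 1.13e-08, and adjusted p = 0.211 with an estimated correlation). In the cell cycle list 22 of 35 rose and none fell, also adjusted over the list alone, with a median of 0.25 (adjusted p = 1.75e-08, and adjusted p = 0.211 with an estimated correlation). Examples are the replication helicase gene Mcm6 (0.97 ± 0.05) and the ribonucleotide reductase gene Rrm2 (0.73 ± 0.05). Of 42 cAMP-induced genes 24 rose and 5 fell before any isoproterenol was given, also adjusted over the list alone, with a median of 0.28 (adjusted p = 3.55e-05, and adjusted p = 0.384 with an estimated correlation). Among them Egr1 was 6.77-fold higher (2.76 ± 0.13), Egr2 3.37-fold (1.75 ± 0.12) and Fos 3.23-fold (1.69 ± 0.13). Dusp1 did not pass (-0.14 ± 0.10, adjusted p = 0.34), but was called lower without TBLR1 replicate 1 (-0.31, adjusted p = 0.00151). That array lay highest on the list. Relative to the untreated control arrays, the list mean was 0.46, 0.293 and 0.271 on the 3 TBLR1 arrays, where Fos read 10.22, 9.63 and 9.58.

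Matrix genes went both ways. The collagen cross-linking enzyme gene Lox fell by 1.77 ± 0.08 and the proteoglycan gene Lum by 1.22 ± 0.06, whereas Thbs1 (2.26 ± 0.13) and Tnc (1.28 ± 0.07) rose. In total 24 of 37 matrix genes fell and 6 rose, or 25 and 7 adjusted over the list alone (median -0.19, adjusted p = 0.000208, and adjusted p = 0.547 with an estimated correlation). Markers of preadipocytes and fibroblasts were not called as a list (median 0.03, adjusted p = 0.461), with 10 of 25 higher and 8 lower, also adjusted over the list alone. The smooth muscle actin gene Acta2 (1.29 ± 0.05) and Tagln (1.27 ± 0.06) rose most. Respiratory chain genes fell slightly, 24 of 49 with 2 higher, also adjusted over the list alone, with a median of -0.09 (adjusted p = 0.00303, and adjusted p = 0.547 with an estimated correlation). Ndufs1 fell by 0.46 ± 0.04. The median of the respiratory chain list was -0.046 after cyclic loess and -0.016 with hybridisation control centring, which moved the median of all genes from -0.01 to 0.06. With that centring the adipocyte and matrix lists read -0.138 and -0.123. Heat shock genes, among them Dnajb1 (0.47 ± 0.06), rose in 9 of 16 cases and fell in 2, or 10 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.00208, and adjusted p = 0.211 with an estimated correlation).

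In all, 5756 genes changed without isoproterenol, 37.7% of those tested, 2701 higher and 3055 lower. Of these, 613 changed by at least 1.5-fold and 146 by at least 2-fold. In the same arrays the excess of actin signal at the 3' end, a sign of RNA quality, differed by -0.049. Over all genes tested, the arrays of the groups did not overlap for 46.9%, where chance gives 10%. Of 36 lists 11 were called, 4 up and 7 down, and 0 with an estimated correlation. Other splits of the same 6 arrays, with the effect of the shRNA left in the values, gave 0 genes at most and up to 13 called lists. Centring on the hybridisation controls, chosen after seeing the data, gave 4987 genes of which 66.6% were higher, against 46.9% in the deposited scaling, so the balance of rises and falls among small changes depends on the scaling.

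With isoproterenol present, the difference between the shRNAs had a similar pattern. Ifit2 was 23.9-fold higher (4.58 ± 0.15), Ccl5 21.0-fold (4.39 ± 0.10), Cxcl10 18.3-fold (4.19 ± 0.17) and Ifit1 8.78-fold (3.14 ± 0.23). Of the 30 interferon genes 28 rose and 1 fell, also adjusted over the list alone, with a median of 2.14 (adjusted p = 1.52e-21, and adjusted p = 0.161 with an estimated correlation). Of 16 macrophage markers 2 rose, Cd14 (0.69 ± 0.09) and Ctss (0.33 ± 0.07), and Csf1r fell (-0.22 ± 0.04), also adjusted over the list alone; with hybridisation control centring Csf1r read -0.11 (adjusted p = 0.164). Cholesterol synthesis genes fell in 16 of 17 cases, also adjusted over the list alone (median -1.01, adjusted p = 7.32e-15, and adjusted p = 0.0808 with an estimated correlation), led by Hsd17b7 (-1.62 ± 0.05) and Tm7sf2 (-1.46 ± 0.06). The largest falls included the RNA-binding protein gene Bicc1 (-1.83 ± 0.04), Lox (-1.78 ± 0.08), the lactonase gene Pon2 (-1.62 ± 0.05) and Retn (-1.60 ± 0.09).

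Under isoproterenol, genes of lipid release and triglyceride synthesis were lower with TBLR1 shRNA. Some were already lower without it, where neither list was called. Relative to the untreated control arrays, the untreated TBLR1 arrays had means of -0.111 ± 0.026 for lipolysis and -0.109 ± 0.014 for triglyceride synthesis (SD, n = 3). On these arrays Lipe read 10.955, 10.918 and 10.891, against 11.43, 11.514 and 11.51 on the untreated control arrays. Pnpla2, Ces1f and Gpat3 were also lower then, whereas Pck1 was higher. Of 18 lipolysis genes 11 fell and 3 rose, also adjusted over the list alone, with a median of -0.30. Lipe, which encodes hormone-sensitive lipase, fell by 0.49 ± 0.06 (adjusted p = 2.07e-06), Pnpla2, which encodes adipose triglyceride lipase, fell by 0.44 ± 0.04 (adjusted p = 1.22e-07), and the carboxylesterase gene Ces1f fell by 0.97 ± 0.07. The list was called (adjusted p = 0.00475, and adjusted p = 0.176 with an estimated correlation). Triglyceride synthesis genes fell in 13 of 22 cases and rose in 4, also adjusted over the list alone (median -0.16, adjusted p = 0.0101, and adjusted p = 0.133 with an estimated correlation), with Pck1, the glyceroneogenic enzyme gene, at -1.03 ± 0.08 and Gpat3 at -0.87 ± 0.04. Of 27 PPARγ targets 13 fell and 5 rose, also adjusted over the list alone, among them the lipid droplet gene Cidec (-0.91 ± 0.05). Their median was -0.11 (adjusted p = 0.0306, and adjusted p = 0.161 with an estimated correlation). This call ended after cyclic loess (adjusted p = 0.066), and the median was 0.00 with hybridisation control centring. Of 34 adipocyte markers 24 fell, also adjusted over the list alone (median -0.29, adjusted p = 8.4e-10, and adjusted p = 0.0808 with an estimated correlation).

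Further metabolic lists were lower in the same comparison. Fatty acid synthesis genes fell in 14 of 19 cases and rose in 3, or 15 and 3 adjusted over the list alone (median -0.52, adjusted p = 4.29e-05, and adjusted p = 0.161 with an estimated correlation), with Acss2 at -1.28 ± 0.06. Of 19 branched-chain amino acid genes 17 fell, or 18 adjusted over the list alone (median -0.42, adjusted p = 8.4e-10, and adjusted p = 0.161 with an estimated correlation), with Pccb at -1.05 ± 0.05 and Aldh6a1 at -0.94 ± 0.06. Hypoxia genes fell in 12 of 20 cases and rose in 1, or 12 and 2 adjusted over the list alone (median -0.32, adjusted p = 0.0117, and adjusted p = 0.411 with an estimated correlation), including the angiogenic factor gene Vegfa (-0.82 ± 0.05). Respiratory chain genes fell in 30 of 49 cases and rose in 2, or 31 and 2 adjusted over the list alone (median -0.15, adjusted p = 8.12e-06, and adjusted p = 0.283 with an estimated correlation). The TCA cycle list fell in 12 of 22 cases and rose in 2, or 13 and 2 adjusted over the list alone (median -0.15, adjusted p = 0.0117, and adjusted p = 0.456 with an estimated correlation), with the pyruvate carboxylase gene Pcx at -0.76 ± 0.04; its call ended after cyclic loess (adjusted p = 0.0624). Matrix genes fell in 23 of 37 cases and rose in 6, also adjusted over the list alone (median -0.18, adjusted p = 0.0025, and adjusted p = 0.503 with an estimated correlation).

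Cell cycle genes were again higher, 25 of 35 with 1 lower, or 25 and 2 adjusted over the list alone (median 0.25, adjusted p = 2.9e-08, and adjusted p = 0.161 with an estimated correlation). In total 6372 genes changed with isoproterenol present, 41.7% of those tested, 2975 higher and 3397 lower, with 823 at 1.5-fold or more and 210 at 2-fold or more. Arrays did not overlap between the groups for 49.1% of all genes tested, against 10% by chance. Of 36 lists 14 were called, 2 up and 12 down, and 0 with an estimated correlation. Centring on the hybridisation controls moved the median of all genes to 0.10 from -0.01. It gave 6814 genes of which 75% were higher, against 46.7% in the deposited scaling. The controls read 11.28 ± 0.081 with control and 11.168 ± 0.042 with TBLR1 shRNA (SD, n = 3). This centring thus carries their spread between arrays into every gene. With the same centring the medians were -0.183 for lipolysis, -0.181 for adipocyte markers, -0.209 for hypoxia, -0.068 for matrix genes, -0.047 for triglyceride synthesis, -0.037 for the respiratory chain and -0.036 for the TCA cycle. All values here are relative to the deposited, quantile normalised scale. Across genes the effects of the TBLR1 shRNA without and with isoproterenol, which share no array, correlated at 0.918 (Pearson) and 0.788 (Spearman); genes are not independent replicates. Both comparisons had 2199 genes higher and 2457 lower, where independent lists would share 526 and 680, and 60 genes changed in opposite directions.

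**Figure D2:**
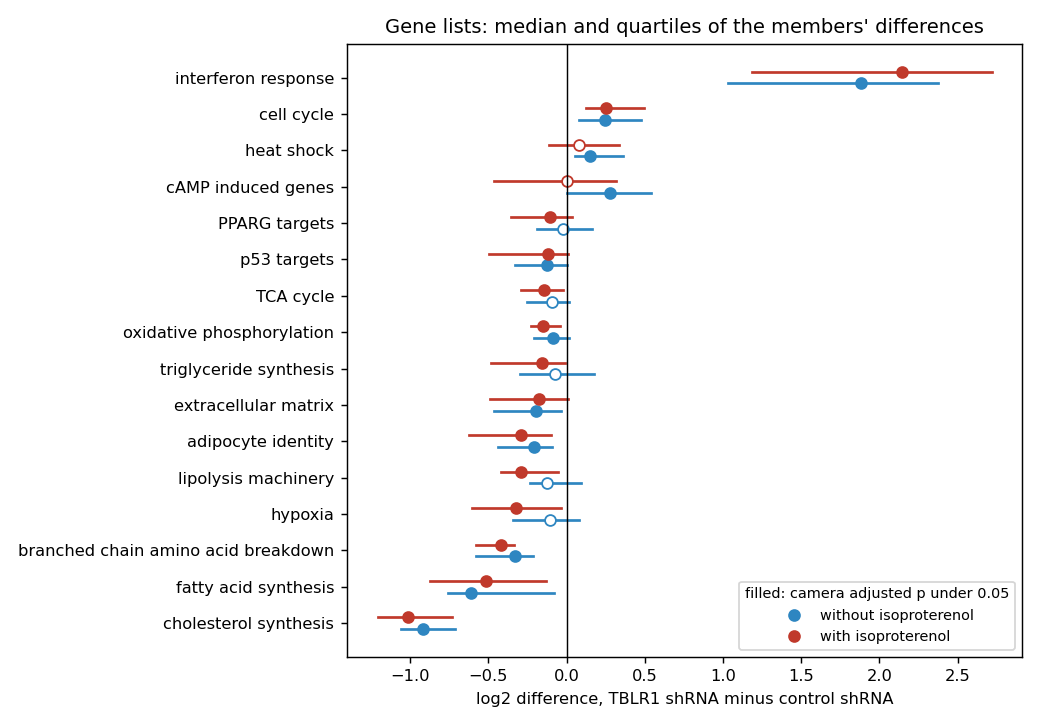
Median (points) and quartiles (lines) of the log2 differences between TBLR1 shRNA and control shRNA (horizontal axis) over the measured members of each gene list called in at least 1 of the treatments; filled points are lists called by camera, blue without and red with isoproterenol. The interferon response list lies at medians of 1.88 and 2.14, and cholesterol synthesis at -0.92 and -1.01.

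Isoproterenol given to cells with control shRNA raised known targets of cAMP signalling. Nr4a1, an orphan nuclear receptor gene, rose 8.18-fold (3.03 ± 0.09), the repressor gene Nfil3 rose 7.99-fold (3.00 ± 0.07), the coactivator gene Ppargc1a rose 7.16-fold (2.84 ± 0.07), the insulin receptor substrate gene Irs2 rose 6.03-fold (2.59 ± 0.09) and Pck1 rose 5.5-fold (2.46 ± 0.08). Of 42 cAMP-induced genes 29 rose and 1 fell, or 30 and 2 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 4.9e-32, and adjusted p = 0.0198 with an estimated correlation). The transcription factor gene Snai2 (-1.17 ± 0.07), Mylip (-1.09 ± 0.08) and the immune checkpoint ligand gene Cd274 (-1.01 ± 0.10) were among the largest falls.

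Lipid genes responded in part. In the lipolysis list 7 of 18 rose and none fell, or 8 adjusted over the list alone (median 0.09, adjusted p = 4.23e-05, and adjusted p = 0.0964 with an estimated correlation). Hilpda, whose product inhibits adipose triglyceride lipase, rose by 1.88 ± 0.06 and Hcar2, an antilipolytic receptor gene, by 1.45 ± 0.08. G0s2, which encodes another inhibitor of that lipase, rose by 0.40 ± 0.11 (adjusted p = 0.0216). G0s2 lost its call with trend and robust moderation (0.0792), without control replicates 1 or 2 before isoproterenol (0.0606 and 0.112, at 0.39 and 0.25) and without control replicates 2 or 3 after it (0.0732 and 0.0579). Triglyceride synthesis genes rose in 8 of 22 cases and none fell, or 9 and 1 adjusted over the list alone, with Gpat3 at 0.73 ± 0.04 and Acsl4 at 0.64 ± 0.06 (median 0.08, adjusted p = 4.23e-05, and adjusted p = 0.0198 with an estimated correlation). Of 27 PPARγ targets 8 rose, also adjusted over the list alone, including Pdk4 (1.93 ± 0.07) and Angptl4 (0.60 ± 0.05). The list was called (median 0.04, mean 0.27, adjusted p = 0.000249, and adjusted p = 0.0198 with an estimated correlation). Thermogenic genes rose in 4 of 21 cases, also adjusted over the list alone, among them Ucp1 (0.31 ± 0.06) and Fgf21 (0.58 ± 0.05). Fgf21 was dim, at 6.24, 6.207 and 6.178 on the untreated control arrays, under the arrays' lower quartile of 6.252. The list had a median of 0.03 (adjusted p = 0.0184, and adjusted p = 0.353 with an estimated correlation). That call ended without the lowest 33% of genes by level (adjusted p = 0.0772), without control replicate 2 before isoproterenol (0.0638) or without control replicate 2 after it (0.0745). The lipolysis median was 0.174 without control replicate 3 before isoproterenol. Under hybridisation control centring, which moved the median of all genes to -0.052, the lipolysis and triglyceride medians were 0.045 and 0.033. Those of the heat shock, unfolded protein and hypoxia lists were 0.027, 0.027 and 0.021, and those of the PPARγ, thermogenic, glucocorticoid and matrix lists turned to -0.01, -0.02, -0.01 and -0.01.

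Stress and hormone-responsive lists also rose with control shRNA. Glucocorticoid targets rose in 8 of 19 cases and fell in 2, also adjusted over the list alone, with Dusp1 at 1.13 ± 0.10 and Klf9 at 0.79 ± 0.04 (median 0.04, mean 0.28, adjusted p = 0.000233, and adjusted p = 0.0964 with an estimated correlation). Heat shock genes rose in 5 of 16 cases, or 6 adjusted over the list alone (median 0.08, adjusted p = 0.000266, and adjusted p = 0.0964 with an estimated correlation), led by Bag3 (1.14 ± 0.05). Hypoxia genes rose in 8 of 20 cases, or 9 with 1 lower adjusted over the list alone (median 0.07, adjusted p = 0.000829, and adjusted p = 0.344 with an estimated correlation), with Ankrd37 at 1.16 ± 0.10 and Vegfa at 0.65 ± 0.05. Of the untreated control arrays, replicate 3 lay near the treated ones: the mean of the hypoxia list, relative to the mean of the untreated control arrays, was -0.092, -0.097 and 0.189 without isoproterenol and 0.245, 0.296 and 0.221 with it. The median of the hypoxia list was 0.27 without that array, and 0.002 and 0.004 without control replicates 1 and 2 before isoproterenol, still called. The unfolded protein response list rose in 6 of 23 cases and fell in 2, or 8 and 2 adjusted over the list alone (median 0.08, adjusted p = 0.0141, and adjusted p = 0.166 with an estimated correlation). Ppp1r15a rose by 1.17 ± 0.05, whereas Herpud1 (-0.82 ± 0.05) and Ddit3 (-0.81 ± 0.05) were the members that fell. Matrix genes rose in 8 of 37 cases and fell in 1, also adjusted over the list alone (median 0.03, adjusted p = 0.0265, and adjusted p = 0.742 with an estimated correlation). That call ended without control replicate 1 before isoproterenol (adjusted p = 0.0878), control replicate 1 after it (0.134) or the lowest 33% of genes by level (0.0543).

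Interferon genes were the list that fell with isoproterenol under control shRNA. Of 30 members 7 fell and none rose, also adjusted over the list alone, among them Cxcl10 (-0.96 ± 0.17), Usp18 (-0.67 ± 0.14) and Irf9 (-0.53 ± 0.10). Ifit1 fell by 0.98 ± 0.23, with an adjusted p = 0.0613 when variances were moderated with trend and robust settings. The median was -0.19 (adjusted p = 0.000454, and adjusted p = 0.742 with an estimated correlation), and without control replicate 1 before isoproterenol it was -0.07 with an adjusted p = 0.119, and -0.31 without control replicate 3. The arrays overlapped. Relative to the untreated control arrays, the list mean was 0.275, -0.03 and -0.245 without isoproterenol and -0.027, -0.384 and -0.332 with it. Replicate 1 was the highest in each group, also with TBLR1 shRNA, and the labels do not say what a replicate number shares. In all, 2833 genes changed, 18.6% of those tested, 1175 higher and 1658 lower, and 189 by at least 1.5-fold, of which 164 were higher and 25 lower. Groups did not overlap for 33.2% of all genes tested, against 10% by chance. Of 36 lists 11 were called, 10 up and 1 down, and 3 with an estimated correlation. By fry 2 of these 11 did not pass, the interferon (adjusted p = 0.144) and matrix genes (0.125). With hybridisation control centring 2463 genes changed and 25.2% of them were higher, against 41.5% in the deposited scaling.

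One of 2 signs of RNA quality moved with isoproterenol and, in untreated cells, with the shRNA, in the same arrays as the lists of those comparisons. The signal of the actin control probe sets at the 3' end exceeded that at the 5' end by 0.94 ± 0.02 (SD, n = 3) with control shRNA and 0.89 ± 0.02 with TBLR1 shRNA before isoproterenol, and by 1.02 ± 0.03 and 1.02 ± 0.03 after it. The difference of 0.10 gave an exact permutation p = 0.005, two-sided, the smallest the arrangements allow, against p = 0.135 for the difference of -0.03 between the shRNAs over both treatments. Without isoproterenol the actin excess was lower on all 3 TBLR1 arrays (0.885, 0.877 and 0.912) than on all 3 control arrays (0.928, 0.936 and 0.957), a difference of -0.049 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow), and with isoproterenol the difference was -0.004 (exact permutation p = 1). For the Gapdh control probe sets the same excess was 0.03 ± 0.03 and 0.04 ± 0.02 before isoproterenol and 0.01 ± 0.04 and 0.06 ± 0.08 after it. No difference was detected with isoproterenol (0.001, exact permutation p = 0.99) or between the shRNAs (0.03, exact permutation p = 0.37).

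In cells with TBLR1 shRNA, isoproterenol raised the same kind of genes by smaller amounts. Nfil3 rose 3.8-fold (1.93 ± 0.07), Nr4a1 3.61-fold (1.85 ± 0.09), Ppargc1a 3.36-fold (1.75 ± 0.07), Irs2 2.25-fold (1.17 ± 0.09) and Pck1 1.86-fold (0.89 ± 0.08). Of 42 cAMP-induced genes 29 rose and none fell, or 34 and 1 adjusted over the list alone, with a median of 0.50 (adjusted p = 1.61e-38, and adjusted p = 0.0241 with an estimated correlation). Triglyceride synthesis genes rose in 5 of 22 cases and fell in 2, or 6 and 2 adjusted over the list alone (median 0.02, adjusted p = 0.00901, and adjusted p = 0.127 with an estimated correlation), with Gpat3 at 0.67 ± 0.04 and Dgat1 at 0.46 ± 0.04. Among lipolysis genes Hilpda (2.83-fold) and Hcar2 (2-fold) rose most, with 5 of 18 higher and 1 lower, or 6 and 1 adjusted over the list alone. The median of the lipolysis list was 0.01 (0.00 with hybridisation control centring) at an adjusted p = 0.0491, and adjusted p = 0.433 with an estimated correlation. This call ended with only the 6 arrays compared (adjusted p = 0.0724), with array weights (0.051), without the lowest 33% of genes by level (0.0749), without control replicate 2 before isoproterenol (0.0574), without control replicates 1, 2 or 3 after it (0.0571, 0.0622 and 0.0535), without TBLR1 replicate 3 before it (0.0514) and without TBLR1 replicate 1 after it (0.112).

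Other lists moved little in these cells. Breakdown genes of branched-chain amino acids fell in 7 of 19 cases, or 9 adjusted over the list alone (median -0.12, adjusted p = 9.02e-06, and adjusted p = 0.379 with an estimated correlation), with Dbt at -0.38 ± 0.07 and Aldh6a1 at -0.30 ± 0.06. Respiratory chain genes had a median of -0.08 with 3 of 49 lower, Uqcrh among them (-0.20 ± 0.04), or 2 adjusted over the list alone (adjusted p = 3.67e-06, and adjusted p = 0.379 with an estimated correlation), and the TCA cycle list a median of -0.07 with 1 of 22 lower, also adjusted over the list alone (adjusted p = 0.00549, and adjusted p = 0.433 with an estimated correlation). The latter was the citrate synthase gene Cs (-0.16 ± 0.04, adjusted p = 0.0253), which lost its call without TBLR1 replicates 2 or 3 before isoproterenol (0.0799 and 0.113), TBLR1 replicates 1 or 3 after it (0.0555 and 0.0918), after cyclic loess (0.0631) and with hybridisation control centring (0.137). Lists called up were glucocorticoid targets with 8 of 19 higher and 2 lower, or 10 and 3 adjusted over the list alone (median 0.14, adjusted p = 4.14e-05, and adjusted p = 0.127 with an estimated correlation), and matrix genes with 5 of 37 higher, or 6 adjusted over the list alone (median 0.08, adjusted p = 0.000115, and adjusted p = 0.433 with an estimated correlation). Also called up were preadipocyte and fibroblast markers with 4 of 25 higher, also adjusted over the list alone, such as Ccn1 (0.76 ± 0.13) and Ccn2 (0.57 ± 0.12; list median 0.10, adjusted p = 0.000983, and adjusted p = 0.39 with an estimated correlation). Targets of ATF4 followed, with 8 of 30 higher and 1 lower, or 11 and 4 adjusted over the list alone (median 0.05, adjusted p = 0.00549, and adjusted p = 0.433 with an estimated correlation), such as Atf3 (0.58 ± 0.08), and so did heat shock genes with 3 of 16 higher and 1 lower, or 5 and 1 adjusted over the list alone (median 0.08, adjusted p = 0.00968, and adjusted p = 0.379 with an estimated correlation). After cyclic loess the median of the TCA cycle list was -0.045 and that of the ATF4 targets 0.077. The largest falls were those of Mylip (-0.90 ± 0.08), the acute phase gene Saa3 (-0.67 ± 0.13) and Glcci1 (-0.64 ± 0.07).

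In all, 1353 genes changed with isoproterenol under TBLR1 shRNA, 8.86% of those tested, 624 higher and 729 lower, and 94 by at least 1.5-fold, of which 91 were higher. Groups did not overlap for 25.2% of all genes tested, against 10% by chance. Of 36 lists 11 were called, 8 up and 3 down, and 1 with an estimated correlation. By fry 2 of these 11 did not pass, ATF4 targets (adjusted p = 0.0573) and matrix genes (0.0703). The count fell to 834 without TBLR1 replicate 2 before isoproterenol, to 752 without TBLR1 replicate 3 before it and to 873 without TBLR1 replicate 2 after it. After cyclic loess, chosen after seeing the data, 56.5% of 1321 genes were higher, against 46.1% of the 1353.

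The difference between the isoproterenol responses was tested directly. Pck1 had the largest difference, a rise 2.96-fold smaller with TBLR1 shRNA (-1.57 ± 0.11, adjusted p = 1.62e-06), and other lower responses were those of Irs2 (-1.42 ± 0.12), Fos (-1.29 ± 0.18), Nr4a1 (-1.18 ± 0.12), Ppargc1a (-1.09 ± 0.10) and Nfil3 (-1.07 ± 0.11; adjusted p from 1.37e-05 to 0.00108). Prom1 (-1.03 ± 0.07) rose with control shRNA from a mean of 6.55 to 7.63 but read 6.28 and 6.33 with TBLR1 shRNA. Levels of Nr4a1 with isoproterenol were nearly the same under both shRNAs (11.36 ± 0.11 and 11.40 ± 0.08, SD), since it started at 8.33 ± 0.09 and 9.55 ± 0.21. Pck1 started at 7.89 ± 0.09 and 8.42 ± 0.02 and ended at 10.35 ± 0.21 and 9.31 ± 0.04. Of 42 cAMP-induced genes 17 had a lower and 1 a higher response, or 20 and 3 adjusted over the list alone, with a median of -0.24 (adjusted p = 5.03e-11, and adjusted p = 0.191 with an estimated correlation). The median was -0.145 without TBLR1 replicate 1 before isoproterenol and -0.157 without control replicate 3 before it. The mean of the list, relative to the untreated control arrays, was 0.34 ± 0.10 (SD, n = 3) with TBLR1 shRNA before isoproterenol. It reached 0.94 ± 0.04 with control and 0.97 ± 0.03 with TBLR1 shRNA after it. Between the shRNAs with isoproterenol 14 of the 42 genes were higher and 16 lower, or 15 and 16 adjusted over the list alone. The list was not called (median 0.005, mean 0.034, with the test pointing down, adjusted p = 0.89).

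Lists of lipid handling had lower responses with TBLR1 shRNA. Of 27 PPARγ targets 2 passed, Pck1 and Pdk4 (-0.77 ± 0.10), also adjusted over the list alone, and the list had a median of -0.06 (adjusted p = 0.000208, and adjusted p = 0.0474 with an estimated correlation). Triglyceride synthesis genes had 3 of 22 lower, also adjusted over the list alone, among them Lpin1 (-0.43 ± 0.07), with a median of -0.07 (adjusted p = 0.00567, and adjusted p = 0.143 with an estimated correlation). Lpin1 rose with control shRNA (0.24, adjusted p = 0.00235) and fell with TBLR1 shRNA (-0.18, adjusted p = 0.0305). The fall lost its call without TBLR1 replicates 2 or 3 before isoproterenol (adjusted p = 0.1 and 0.124), TBLR1 replicates 1, 2 or 3 after it (0.0625, 0.0841 and 0.0838), after cyclic loess (0.0621) and with hybridisation control centring (0.0739), at -0.19 to -0.16. Thermogenic genes had 3 of 21 lower, also adjusted over the list alone, with Ppargc1b at -0.54 ± 0.09 and a median of -0.04 (adjusted p = 0.00642, and adjusted p = 0.281 with an estimated correlation). Adipocyte markers had 2 of 34 lower, or 4 adjusted over the list alone, with a median of -0.05 (adjusted p = 0.00184, and adjusted p = 0.281 with an estimated correlation). Respiratory chain genes had 0 of 49 past the test in limma and a median of -0.06 (adjusted p = 0.000771, and adjusted p = 0.392 with an estimated correlation). Hypoxia genes had 5 of 20 lower, also adjusted over the list alone, with Ankrd37 at -0.69 ± 0.14, Vegfa at -0.52 ± 0.07 and a median of -0.14 (adjusted p = 0.00026, and adjusted p = 0.281 with an estimated correlation). The hypoxia median was -0.021, -0.06 and -0.289 without control replicates 1, 2 and 3 before isoproterenol. With hybridisation control centring the medians of the other lists lay closer to 0, at -0.022 for PPARγ targets, -0.027 for triglyceride synthesis, -0.001 for thermogenic genes, -0.004 for adipocyte markers and -0.021 for the respiratory chain, while that of all genes moved from 0.001 to 0.042.

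The lipolysis list had a median of -0.12 (adjusted p = 0.000238, and adjusted p = 0.191 with an estimated correlation), with 2 of 18 lower, also adjusted over the list alone. These were Hcar2 (-0.45 ± 0.11, adjusted p = 0.0385) and Hilpda (-0.38 ± 0.09, adjusted p = 0.0266). Hilpda lost its call without control replicate 2 or 3 before isoproterenol (adjusted p = 0.0699 and 0.0572), control replicate 3 after it (0.0727), TBLR1 replicate 2 or 3 after it (0.066 and 0.0725), or with hybridisation control centring (0.0518). The list's median was -0.082 with that centring. Hcar2 lost it without control replicates 2 or 3 before isoproterenol (0.107 and 0.0841), TBLR1 replicates 2 or 3 before it (0.103 and 0.0566), control replicates 1 or 3 after it (0.0885 and 0.0923) and TBLR1 replicates 2 or 3 after it (0.0966 and 0.0687).

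Positive differences were those of interferon genes, with a median of 0.27 over 30 members and 2 of them higher, Cxcl10 (1.13 ± 0.24, adjusted p = 0.0223) and Stat2 (0.35 ± 0.08, adjusted p = 0.0403), or 4 adjusted over the list alone (list adjusted p = 8.42e-07, and adjusted p = 0.392 with an estimated correlation). For this list the difference was mostly a fall with control shRNA. Relative to the untreated control arrays, the list mean with control shRNA and isoproterenol was -0.247 ± 0.19 (SD, n = 3). With TBLR1 shRNA it was 1.726 ± 0.049 before isoproterenol and 1.783 ± 0.043 after it. The interferon median was 0.116 and 0.412 without control replicates 1 and 3 before isoproterenol. Cxcl10 lost its call with trend and robust moderation (adjusted p = 0.139), without TBLR1 replicates 2 or 3 before isoproterenol (0.052 and 0.0649), control replicates 2 or 3 after it (0.064 and 0.0643) and TBLR1 replicate 3 after it (0.0569). Stat2 lost its call without any 1 of 9 of the 12 arrays (adjusted p from 0.0513 to 0.111, with differences of 0.29 to 0.36) and after cyclic loess (0.0554). NF-κB genes had 2 of 33 higher, Cxcl10 and Ccl5 (0.55 ± 0.14, adjusted p = 0.0479), or 8 adjusted over the list alone (median 0.10, adjusted p = 0.0024, and adjusted p = 0.432 with an estimated correlation; without control replicate 2 before isoproterenol adjusted p = 0.0574). Ccl5 lost its call with trend and robust moderation (0.124), after cyclic loess (0.0505) and without any 1 of 10 of the 12 arrays (0.0669 to 0.134, with differences of 0.44 to 0.57). Preadipocyte and fibroblast markers had 2 of 25 higher, or 3 adjusted over the list alone, with Pdgfra at 0.46 ± 0.06 (median 0.06, adjusted p = 0.0103, and adjusted p = 0.392 with an estimated correlation; 0.0505 without control replicate 2 before isoproterenol and 0.0502 without TBLR1 replicate 2 after it; median 0.099 with hybridisation control centring). With control shRNA Pdgfra read 8.834, 8.891 and 8.832 before isoproterenol and 8.473, 8.336 and 8.428 after it. With TBLR1 shRNA it read 8.461, 8.443 and 8.42 before and 8.416, 8.525 and 8.455 after. Outside these lists the stress genes Ddit3 (0.73 ± 0.07) and Herpud1 (0.51 ± 0.07), which fell with control shRNA, and the kinase gene Sgk1 (0.69 ± 0.11) had positive differences. Rasd1 (-1.03 ± 0.08), Plk3 (-0.97 ± 0.09), Noct (-0.92 ± 0.16) and Cenpu (-1.10 ± 0.11) had negative ones.

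Some further lists called lower lost the call when single arrays were left out. Breakdown genes of branched-chain amino acids (median -0.06, adjusted p = 0.00767, and adjusted p = 0.426 with an estimated correlation) had 0 of 19 past the test in limma and lost the call without control replicate 2 before isoproterenol (0.0739). Cholesterol synthesis (median -0.07, adjusted p = 0.0103, and adjusted p = 0.392 with an estimated correlation) had 0 of 17, or 1 lower adjusted over the list alone, and lost it without control replicate 1 before isoproterenol (0.106). Fatty acid oxidation (median -0.07, adjusted p = 0.0162, and adjusted p = 0.432 with an estimated correlation) had 1 of 26 lower, also adjusted over the list alone, and lost it without replicate 2 of the control or TBLR1 cells before isoproterenol (0.111 and 0.0621) or of the control cells after it (0.132). Glycolysis (median -0.07, adjusted p = 0.0103, and adjusted p = 0.366 with an estimated correlation) had 2 of 14 lower, also adjusted over the list alone, and lost it without control replicate 1 or 2 before isoproterenol (0.0569 and 0.0683). Heat shock genes (median -0.04, adjusted p = 0.0239, and adjusted p = 0.307 with an estimated correlation) had 2 of 16 lower, also adjusted over the list alone, with Bag3 at -0.65 ± 0.07. Insulin signalling (median -0.04, adjusted p = 0.031, and adjusted p = 0.281 with an estimated correlation) had 1 of 17 lower, also adjusted over the list alone. Both lost their calls without control replicate 1 (0.0551 and 0.0569) or TBLR1 replicate 1 before isoproterenol (0.12 and 0.11) and TBLR1 replicate 1 after it (0.0749 and 0.0837), heat shock also without control replicate 3 before it (0.0528) and with array weights (0.0521), and insulin signalling without the lowest 33% of genes by level (0.0674). With hybridisation control centring their medians were 0.00 and 0.01, and those of branched-chain amino acid breakdown, cholesterol synthesis, fatty acid oxidation and glycolysis -0.021, -0.024, -0.024 and -0.028. Without control replicate 3 before isoproterenol the glycolysis median was -0.205.

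Across all genes tested, the response to isoproterenol differed between the shRNAs for 366 genes, 2.4% of those tested, 163 higher and 203 lower, and 48 by at least 1.5-fold, of which 35 were lower. Of 36 lists 17 were called, 3 up and 14 down, and 1 with an estimated correlation; relabelled arrays gave up to 16. By fry 7 of the 17 passed and 10 did not. The latter were interferon (adjusted p = 0.23), NF-κB (0.271), hypoxia (0.141), cholesterol synthesis (0.198), fatty acid oxidation (0.223), glycolysis (0.191), branched-chain amino acid breakdown (0.208), the respiratory chain (0.0918), thermogenic genes (0.0753) and preadipocyte and fibroblast markers (0.173). With hybridisation control centring 252 genes differed and 59.9% were higher, against 44.5% in the deposited scaling. The count fell to 235 without control replicate 2, 221 without TBLR1 replicate 2 and 237 without TBLR1 replicate 3 before isoproterenol, and to 232 and 218 without control replicates 2 and 3 and 228 and 198 without TBLR1 replicates 2 and 3 after it. The responses under the 2 shRNAs, which share no array, correlated across genes at 0.728 (Pearson) and 0.487 (Spearman). Both had 435 genes higher and 513 lower, where independent lists would share 48 and 79, and 4 changed in opposite directions. Among all 1413 genes whose mean response over both shRNAs was a called rise, 72% had a smaller response with TBLR1 shRNA. Among the 2061 with a called fall this was 72.7%, and it held for all 6 with a fall of at least 1.5-fold. Among 113 genes whose mean response over both shRNAs was a rise of at least 1.5-fold, 97 (85.8%) rose less with TBLR1 shRNA, and the slope of their responses was 0.665. The test of the difference was passed by 61 of these 97. Of the 113, 84 had been higher with TBLR1 shRNA beforehand, and under isoproterenol 65 were lower with it, with a median difference of -0.08. In 16 of the 113 the rise was not smaller, and 4 of these, named after their values were seen, passed the test of the difference: Metrnl (0.65 ± 0.09), Thbd (0.63 ± 0.09), Tnfaip6 (0.54 ± 0.11) and D16Ertd472e (0.30 ± 0.06).

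**Figure D3:**
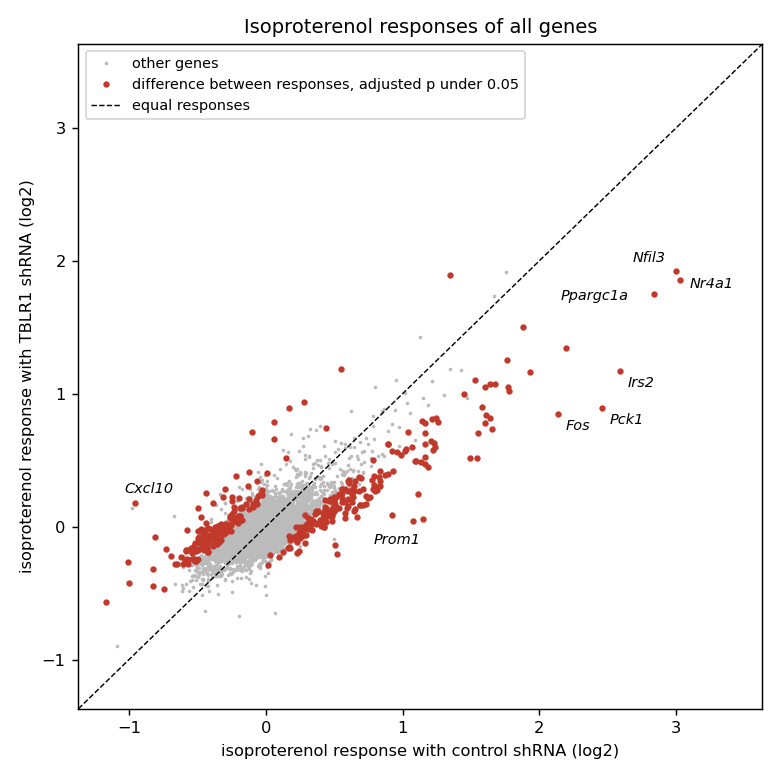
Isoproterenol responses (log2) of all 15267 genes with control shRNA (horizontal axis) and TBLR1 shRNA (vertical axis); red points are the 366 genes whose responses differed (limma, adjusted p under 0.05) and the dashed line marks equal responses. Most genes with a mean rise of at least 1.5-fold, 97 of 113, lie below the line, such as Pck1 at 2.46 and 0.89, while others lie above it, such as Tnfaip6 at 1.35 and 1.89.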

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

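The tests of immune cell RNA, of vector sensing, of a raised starting level, of weaker signalling, of the share of adipocytes and of oxysterols were chosen after the results they bear on had been seen, whereas the test of bright probe sets and the counts over other splits of the arrays were planned.

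The response to isoproterenol differed between the shRNAs, by the test of the difference itself, for 366 genes. Responses were lower with TBLR1 shRNA for Pck1 (-1.57), Irs2 (-1.42), Fos (-1.29), Nr4a1 (-1.18), Cenpu (-1.10), Ppargc1a (-1.09), Nfil3 (-1.07), Prom1 (-1.03), Rasd1 (-1.03), Plk3 (-0.97), Noct (-0.92), Pdk4 (-0.77), Ankrd37 (-0.69), Bag3 (-0.65), Ppargc1b (-0.54), Vegfa (-0.52), Hcar2 (-0.45), Lpin1 (-0.43) and Hilpda (-0.38); all of these rose with control shRNA, and Lpin1 was lower after isoproterenol with TBLR1 shRNA (-0.18, a call that ended without any 1 of 5 arrays). The difference was positive for Cxcl10 (1.13), Ddit3 (0.73), Sgk1 (0.69), Ccl5 (0.55), Herpud1 (0.51), Pdgfra (0.46) and Stat2 (0.35), and for Metrnl (0.65), Thbd (0.63), Tnfaip6 (0.54) and D16Ertd472e (0.30), named after their values were seen. Of these, Cxcl10, Ddit3, Ccl5, Herpud1 and Pdgfra read lower after isoproterenol with control shRNA. Their differences came with a smaller fall, or none, under TBLR1 shRNA and not with a larger rise. The calls of Ccl5, Stat2, Hcar2, Hilpda and Cxcl10 lie near the threshold, and each ended when any 1 of 10, 9, 8, 5 and 5 of the 12 arrays was left out. In those fits the differences were 0.44 to 0.57, 0.29 to 0.36, -0.48 to -0.38, -0.37 to -0.36 and 1.03 to 1.14.

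Among lists, the median difference was -0.24 for cAMP-induced genes, -0.14 for hypoxia, -0.12 for lipolysis, -0.07 each for glycolysis, triglyceride synthesis, cholesterol synthesis and fatty acid oxidation (-0.069, -0.068, -0.066 and -0.065), and -0.06 each for PPARγ targets, branched-chain amino acid breakdown and the respiratory chain (-0.063 in all 3). It was -0.05 for adipocyte markers (-0.045), -0.04 for thermogenic genes (-0.042), heat shock genes (-0.04) and insulin signalling (-0.036). Differences above 0 were those of interferon genes (0.27), NF-κB genes (0.10) and preadipocyte and fibroblast markers (0.057).

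The counts were also taken on relabelled arrays. For the difference between responses, 100 of the 200 possible splits were drawn on values with the additive effects removed. Only 1 of the 100, the real one, gave as many as 366 genes, with 5 as the highest other, a share under 0.05. The difference itself stayed in these values, where it adds to the spread of the other splits and may lower their counts. As the replicates may be technical, the splits may say nothing of differences between cultures. As for lists, 1 of the 100 splits, again the real one, gave as many as 17, with 16 as the highest other and a median of 5, so the count passes the same bound by 1 list only, and relabelled arrays also gave many list calls. The other comparisons are of 3 arrays against 3, where the 10 splits are too few for a share under 0.05. Their values kept the effect of the groups, which a mixed split moves into the spread and, in part, into the difference. The counts of such splits are thus not those of arrays without an effect. TBLR1 shRNA without isoproterenol gave 5756 genes against 0 as the highest other (1 of 10 splits as large) and 11 lists against 13 (6 of 10 splits as large). With isoproterenol it gave 6372 genes against 0 (1 of 10) and 14 lists against 10 (1 of 10). Isoproterenol gave 2833 genes against 1 (1 of 10) and 11 lists against 10 (1 of 10) with control shRNA, and 1353 genes against 1 (1 of 10) and 11 lists against 15 (2 of 10) with TBLR1 shRNA.

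Interferon-induced genes rose with TBLR1 shRNA by a median of 1.88 without isoproterenol. RNA of immune cells in these samples would raise macrophage markers together. The upper quartile of 16 such markers was 0.034, and the abundant macrophage gene Lyz2 changed by 0.05 ± 0.04 at a level in percentile 29.1, but 12 of the 16 lay in the lowest 33% of genes by level and Cd14, in percentile 84.1, rose by 0.45. The markers alone thus leave immune cell RNA open, and other immune cells were not examined. The samples were cultures of a fibroblast line, however, and the labels name no immune cells. The design thus gives no source of such RNA. Sensing of this vector or its shRNA, apart from the loss of TBLR1, cannot be told apart from the knockdown, because the labels give only 1 vector against TBLR1, and the interferon gene Ifnb1, chosen after the values were seen, was higher by 0.221 ± 0.044 (adjusted p = 0.000664). Ifnb1 was itself dim, in percentile 35.3 of genes by level. A release of interferon genes from corepressors that hold TBLR1 is a biological candidate and was not tested.

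Among 113 genes raised by isoproterenol, 85.8% rose less with TBLR1 shRNA. Of the 29 not higher with TBLR1 shRNA beforehand, 79.3% also rose less (95% Wilson interval 61.6 to 90.2). A raised starting level would not give this. For the 84 that started higher it stays open. Under isoproterenol 45.2% of these 84 were lower with TBLR1 shRNA (35 to 55.9), with a median difference of 0.065. The intervals here take genes as independent, though genes of the same arrays vary together. They may therefore be too narrow and do not settle the question. Compression of bright probe sets would spare dimmer genes, yet 80% of the 15 genes under the 75th percentile of level rose less (54.8 to 93). This goes against it as the whole cause, but the 15 genes are few and not independent. Weaker β-adrenergic or cAMP signalling after loss of TBLR1 is a hypothesis that would leave cAMP-induced genes lower under isoproterenol, yet 14 of 42 were higher and 16 lower (median 0.005, quartiles -0.46 and 0.31), and beforehand the list was higher (0.28). As its members went both ways and signalling itself was not measured, it stays open.

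Cholesterol synthesis genes fell with TBLR1 shRNA by a median of 0.92. A smaller share of adipocytes would lower adipocyte markers by about as much, but their lower quartile was -0.439, above that median, which argues against it as the whole cause. An excess of oxysterols, which would also raise LXR targets, stays open: the LXR targets had a median of -0.179 with quartiles of -0.35 and 0.06, members went both ways, and Ch25h, which makes an oxysterol and was chosen after its values were seen, was higher by 0.40 ± 0.06. Less SREBP2 activity may be a candidate explanation and was not tested beyond the list itself.

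Signals also appeared in probe sets outside the tests of genes. Of 1222 probe sets without a gene name, 377 changed with TBLR1 shRNA without isoproterenol, 410 with it, 176 with isoproterenol under control shRNA, 84 under TBLR1 shRNA and 27 in the difference between responses. Of the 61 control probe sets 16, 21 and 6 changed in the first 3 of these comparisons.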

How the results depend on the processing

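Cyclic loess, centring on hybridisation controls and the fit with unnamed probe sets were chosen after the results were seen; the other tests were planned. Of 215 called changes of named genes, 11 lost the call when some 1 array was left out. With trend and robust moderation 4 lost it, after cyclic loess 5 and with hybridisation control centring 12. At an adjusted p under 0.01 the loss was 14, and at 1.5-fold or more it was 57. Array weights and the unnamed probe sets ended 0 calls. Median centring and the mean of probe sets also ended 0, but could change almost nothing. The arrays already shared their median, and only 3 genes had 2 probe sets. None reversed under any alternative. The named genes were mostly chosen as the largest called changes, so these losses do not describe the called genes near the threshold. Of 64 list calls 12 were lost when some 1 array was left out and 59 with an estimated correlation. At an adjusted p under 0.01 the genes were 1828 for isoproterenol with control shRNA, 687 with TBLR1 shRNA and 132 for the difference between responses, and the lists 9 for TBLR1 shRNA with isoproterenol and 11 for the difference. At 1.5-fold or more, counts of genes were 613, 823, 189, 94 and 48 in the order of the 5 comparisons. With an estimated correlation 0, 0, 3, 1 and 1 lists were called in that order, and fry called 24, 28, 17, 14 and 9, without 14 of the 64 list calls, 10 of them in the difference between responses. Leaving out 1 array gave 752 to 1681 genes for isoproterenol with TBLR1 shRNA, 198 to 385 for the difference, 5177 to 5844 and 5829 to 6373 for TBLR1 shRNA, and 2250 to 2900 for isoproterenol with control shRNA. List medians also moved by over 1.5 times when 1 array was left out, beyond those given with the results. For isoproterenol with control shRNA the medians were 0.029 to 0.081 for PPARγ targets, 0.005 to 0.056 for matrix, 0.036 to 0.097 for glucocorticoid, 0.011 to 0.07 for thermogenic and 0.054 to 0.093 for triglyceride synthesis genes. With TBLR1 shRNA they were 0.045 to 0.096 for matrix, 0.06 to 0.116 for preadipocyte and fibroblast, 0.01 to 0.042 for triglyceride synthesis and -0.004 to 0.02 for lipolysis genes. For the difference they were -0.089 to -0.023 for branched-chain amino acid breakdown, -0.124 to -0.037 for cholesterol synthesis, -0.049 to -0.01 for heat shock, 0.059 to 0.139 for NF-κB, -0.068 to -0.025 for insulin signalling, -0.07 to -0.041 for the respiratory chain, 0.053 to 0.111 for preadipocyte and fibroblast, -0.085 to -0.027 for thermogenic and -0.075 to -0.041 for triglyceride synthesis genes. For TBLR1 shRNA they were -0.153 to -0.084 for p53 targets without isoproterenol and -0.174 to -0.084 for PPARγ targets with it. Why the smaller counts moved was not tested, beyond the fewer arrays of each such fit and the stricter thresholds.

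With the replicate block the counts were 5623, 6279, 2723, 1267 and 320 genes and 11, 14, 12, 12 and 17 lists. The block ended the calls of Hcar2 (adjusted p = 0.0504) and Ccl5 (0.0604) in the difference between responses and brought 2 further list calls, insulin signalling for isoproterenol with control shRNA (0.0416 against 0.0521) and NF-κB genes with TBLR1 shRNA (0.0282 against 0.0511). It changed no other call of a named gene or list. The labels do not say what a replicate number shares. Deviations of same-numbered arrays correlated at -0.21 to 0.18 (median 0.0015, 2 of 18 pairs over 0.1) and 1 of 12 arrays correlated best with its own number, so the numbers were not taken as pairs.

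Not run were quantile normalisation, already in the values, pseudocounts, as the values were logarithms, and the removal of probe sets by ending, since the names carry none of those endings. Dim probe sets limit what arrays show: without the lowest 33% of genes by level 4 of 64 list calls were lost, and most macrophage markers lie in that range.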

Other observations

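The test of ERK feedback genes was chosen after Egr1, Egr2 and Fos had been seen, and the lists below were planned.

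Targets of p53 were called lower with TBLR1 shRNA, by amounts that depend on the scaling. Without isoproterenol 10 of 22 fell and 3 rose, or 11 and 3 adjusted over the list alone, among them the stress response gene Sesn1 (-0.86 ± 0.07), Zmat3 (-0.73 ± 0.05), the cell cycle inhibitor gene Cdkn1a (-0.71 ± 0.06) and Ccng1 (-0.71 ± 0.06). The median was -0.13 (camera adjusted p = 0.0138, and adjusted p = 0.211 with an estimated correlation). With isoproterenol 11 fell and 3 rose, also adjusted over the list alone, with a median of -0.12 (adjusted p = 0.0192, and adjusted p = 0.161 with an estimated correlation). Centred on the hybridisation controls, the medians were -0.056 and -0.008.

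Some lists were called in none of the 5 comparisons, and their medians without isoproterenol were small, although single members moved. LXR targets had a median of -0.18 (adjusted p = 0.322), with 7 of 13 lower, such as Mylip (-0.84 ± 0.08), which degrades the LDL receptor, and Nr1h3, the LXRα gene (-0.43 ± 0.06), and 2 higher, Srebf1 and Pltp (0.70 ± 0.04). The oxidative stress list of NRF2 targets had -0.12 (adjusted p = 0.125), with Gstm1 at -0.56 ± 0.04. Clock genes had -0.08 (adjusted p = 0.441), with Rora at -0.61 ± 0.05, and ribosomal protein genes -0.07 (adjusted p = 0.461). Muscle markers had -0.05 (adjusted p = 0.645), with Acta1 at 0.68 ± 0.05, and endothelial markers 0.01 (adjusted p = 0.673), with Flt1 at 0.18 ± 0.04. Wnt targets had 0.01 (adjusted p = 0.282), although Myc rose by 1.31 ± 0.11. Genes of the adrenergic and cAMP machinery had a median of -0.01 but a mean of 0.02 and a test pointing up (adjusted p = 0.462). Genes of the RNA interference machinery had a median of 0.01 and a mean of 0 (adjusted p = 0.74), with Tnrc6b at -0.61 ± 0.05. In the lists of fatty acid oxidation and the TCA cycle, not called here, Cpt1a, the carnitine shuttle enzyme gene, rose by 1.18 ± 0.06 and Idh2 by 0.73 ± 0.05.

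Raised ERK activity may accompany the higher Egr1, Egr2 and Fos in cells with TBLR1 shRNA. Of 14 feedback and target genes of the ERK pathway, 11 were measured outside the cAMP list, and without isoproterenol 8 rose and 1 fell, with a median of 0.21. Camera with an estimated correlation gave p = 0.0335, without adjustment over other lists, and p = 0.0484 with isoproterenol. Dusp6 rose by 2.23 ± 0.13, Dusp5 by 1.20 ± 0.12, Phlda1 by 1.16 ± 0.12 and Fosl1 by 0.93 ± 0.10, whereas Spry1 fell by 0.22 ± 0.08. For isoproterenol with control shRNA camera with an estimated correlation gave p = 0.0399, and for the difference between the responses p = 0.525. The list thus also moves with isoproterenol, and ERK itself was not measured.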
